A study of Mus musculus with 80 samples.

How the data were processed

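Spleen RNA of 40 C57BL/6 mice, 20 males and 20 females, was measured on 80 membrane arrays. Each mouse had 1 array A and 1 array B, each with 8448 cDNA spots. Per the labels' protocols, about 5 µg of total RNA was reverse transcribed into cDNA labeled with 33P-dCTP and hybridized as a single channel. Each array was deposited as a standardized score: every column had mean 0 and standard deviation 1 over its spots, with medians from -0.11 to -0.05 on array A and from -0.08 to -0.01 on array B. The scanner, background correction, normalization and scale before standardization are not given in the sources used here. A difference of 1 is therefore 1 standard deviation of the spots of an array, and no fold change was computed. A rise of 1 transcript's score is relative to the other spots of its array. The number of mice limits the precision, and the depth behind a spot is unknown.

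Mice were grouped by sex and age class from the labels, with 5 mice in each of 8 groups, and each mouse's own age in days was used in the age fits. The description of male old replicate 2 repeats that of another mouse, while its title and characteristics match each other, so the title was followed and the mouse was left out in 1 alternative. Ordered by the running number in their labels, which has gaps, the mice fell into 5 successive sets of 8, each with 1 mouse of every group and called a label run here. That a set was handled together is not stated. These label runs were treated as a batch because they accounted for more variance than random sets of 8, and each comparison was repeated with label run as a block and within each run. Replicate numbers are the numbers of the runs. Values were used as deposited, with no filter on low values in the primary fits. Of the 16896 spots, 9663 carried 1 gene symbol in the platform annotation, 436 several and 6797 none. Entrez identifiers matched for 9641 of the single-symbol spots, and updating the symbols through them against the RefSeq annotation of assembly GRCm38.p6, used for names alone, changed 0. Gene-level values were means of the centered spots of each of 7151 genes, of which 1858 had more than 1 spot.

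Differences were tested with limma (version 3.58.1, R 4.3.3) by lmFit and eBayes with default priors, separately for each array. Two-sided p-values were adjusted by Benjamini-Hochberg over both arrays at a threshold of 0.05, and for genes over all genes. The age trend was a linear fit over all 40 mice with sex as a covariate, per 100 days. Differences between age classes and sexes, and the female minus male contrast of the old minus young adult changes, came from 1 fit of the 8 groups. The difference of age slopes came from a fit with age, sex and their product. The juvenile fit used the 10 juveniles, with age per 10 days and sex. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 21 tested lists of a comparison. They were tested again with an estimated correlation, and with fry, which asks whether the genes of a list move on balance in 1 direction. Of the 28 lists, those with under 5 measured genes had values and counts but no test. The comparisons, their tests, the lists, the rule for naming genes and most alternatives were fixed before the data were examined.

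The lists covered B cells, plasma cells and immunoglobulin, T cells, natural killer cells, erythroid cells, megakaryocytes, neutrophils, macrophages and red pulp, dendritic cells, stroma, endothelium, and pancreatic, adipose and liver tissue. They also covered cell cycle, interferon response, MHC class II, MHC class I, inflammation and complement, oxidative phosphorylation, ribosomal proteins, proteasome, translation factors, heat shock, ER chaperones, antioxidant and iron handling, senescence and p53 targets, and sex-linked genes. The plasma cell and ER lists share Xbp1, Creld2 and Edem1, the macrophage and inflammation lists C1qa, C1qb and C1qc, and the neutrophil and inflammation lists Lcn2 and S100a9. The antioxidant and iron list shares Fth1, Ftl1, Hmox1 and Slc40a1 with macrophages and Prdx2 and Tfrc with erythroid cells, the ER list shares Calr and Pdia3 with MHC class I and P4hb with stroma, the translation list shares Eif2s3x and Eif2s3y with sex-linked genes, and the dendritic and interferon lists share Bst2. Genes were named by rule: up to 12 in each direction with the largest statistics among those past the threshold, with the same direction in both sexes (for the sex comparison, in at least 3 of 4 age classes; no such condition for juveniles and the tests of age by sex). Where fewer than 3 passed, the 3 with the largest statistics in each direction were named as below the threshold. The 4 members with the largest statistics of each list past the threshold, and every sex-linked gene in the sex comparison, were added. Genes named outside the rule are said to be chosen after their values were seen; these include spots called after subtraction of the local median.

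The arrangement of spots is not given. It was inferred after the values were seen from correlations between residuals of spots at each step in the numbering. The median correlation was 0.645 on array A and 0.613 on array B at a step of 22, and 0.618 and 0.576 at a step of 528, against a median of 0.0806 and 0.0595 over the steps examined. This gave 22 panels of 384 spots per array, in 24 rows and 16 columns. The local median of the spots within 2 rows and 2 columns was subtracted in 1 alternative, which lowered the mean standard deviation of a spot over the mice from 0.196 to 0.142. Spots of the same gene on arrays A and B (1497 pairs) had a median correlation over mice of 0.0502, against 0.00298 for shuffled pairs. cDNA spots can bind transcripts of related genes, which was not tested.

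Alternatives were quantile normalization, subtraction of each array's median, leaving out the dimmest spots, label run as a block, array weights, eBayes with trend and robust settings, adjustment within each array table, gene-level values, leaving out the mouse with the conflicting description and leaving out each mouse in turn. For single comparisons they were log2 of age, adult mice alone, a fit without sex, and the mice compared alone. Chosen after seeing the data were the subtraction of the local median, leaving out panels, and a comparison of young adults with the youngest juveniles. The fits were tested on simulated data with independent noise of each spot's own spread and known changes of 0.25, 0.5 and 1, for slopes over the whole range of ages. They found 35.8%, 91% and 97% for old against young adult mice, 62.7%, 97% and 100% for sex, 1.49%, 23.9% and 89.4% for the difference of slopes, and 0%, 16.4% and 86.4% for juveniles. Tables were read with the package data.table (version 1.17.8), and figures were drawn in Python 3.11.15 with matplotlib 3.10.9 and pandas 2.3.3.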

Results

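Spleens of 40 C57BL/6 mice were profiled on a pair of nylon membrane cDNA arrays, array A and array B, giving 80 arrays and 16896 spots per mouse. The mice formed 8 groups of 5, males and females of 4 age classes. Juveniles were 17 to 44 days old, young adults 169 to 194 days, middle-aged mice 476 to 499 days and old mice 704 to 743 days. The deposited values were standardized scores, so every difference below is in units of the standard deviation of all spots on an array, and its relation to a fold change is unknown. Spots with a single gene symbol covered 7151 genes. Pairwise correlations between arrays, taken across spots, ran from 0.82 to 0.987 on array A and from 0.808 to 0.991 on array B. Label run, a set of 8 mice that follow each other in the numbering of the labels and hold 1 mouse of every group, accounted for 35.1% of the variance on array A and 21.6% on array B, against 10.3% and 10.2% for random sets of 8. Age class accounted for 6.34% and 7.18% and sex for 1.32% and 1.64%, and random classes of the same sizes gave 7.74% and 7.78% for age and 2.34% and 2.37% for sex. The number of mice per group limited the precision: the median standard error of a difference between age classes was 0.0782 per spot.

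The first comparison asked which spleen transcripts changed steadily with age from 17 to 743 days. Ighm, the constant region of the IgM heavy chain, rose by 0.149 per 100 days (SE 0.0256, n = 40, adjusted p = 0.0011), and its mean went from -0.353 ± 0.382 in juveniles and -0.369 ± 0.373 in young adults to 0.0752 ± 0.409 in middle-aged and 0.646 ± 0.596 in old mice (SD, n = 10 each). Tle4, a transcriptional corepressor, rose by 0.106 per 100 days (SE 0.0141, adjusted p = 2.07e-05), Irf2bpl by 0.0798 (SE 0.012, adjusted p = 1.65e-04) and Tgfbr3, the TGF-beta co-receptor betaglycan, by 0.0765 (SE 0.0124, adjusted p = 5.77e-04). Txndc5, a disulfide isomerase of the endoplasmic reticulum, rose by 0.0427 (SE 0.00923, adjusted p = 0.0261). The others that rose were Lrrc58 (0.0421), B3galt5, a galactosyltransferase (0.0711), Cfap47 (0.0755), L3mbtl2, a chromatin protein of the Polycomb group (0.0647), and the ubiquitin ligase Znrf2 (0.027). Each of these 10 genes rose in both sexes, and the slope was positive in 5 of 5 label runs, except for Txndc5 with 4 of 5. No gene fell. Of these genes, 8 had their called spot in 1 of 2 small areas, 1 on each membrane. Txndc5 was spotted in another panel. Znrf2 had no called spot of its own: of its 2 spots, that with a slope of 0.0451 (adjusted p = 0.08) lay in the area on array B, in row 24 and column 15 between B3galt5 and Irf2bpl, and the other, outside it, had a slope of 0.00899 (adjusted p = 0.886). After subtraction of the local median of neighboring spots, the calls of Ighm (0.113, adjusted p = 0.107), Tgfbr3 (0.0593, adjusted p = 0.0693), Lrrc58 (0.0289, adjusted p = 0.195), L3mbtl2 (0.0245, adjusted p = 0.0514) and Znrf2 (0.00864, adjusted p = 0.68) were lost.

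Grouped by cell type, the age trend showed a higher plasma cell list, a lower erythroid list, and higher macrophage, inflammation and endoplasmic reticulum (ER) chaperone lists. With an estimated correlation the plasma cell call was kept and the other 4 were lost (adjusted p from 0.0916 to 0.563). The plasma cell and immunoglobulin list had a mean slope of 0.0317 per 100 days, with 5 of 6 members above 0, and passed with camera (adjusted p = 0.00281, and adjusted p = 0.0183 with an estimated correlation). Of its members 2 rose adjusted over the list alone and 1, Ighm, over all genes; Xbp1, the transcription factor of antibody-secreting cells, had a slope of 0.0187 and the ER protein Creld2 one of 0.0223. The inflammation and complement list had a mean slope of 0.0123 with 12 of 13 members above 0 (adjusted p = 0.00281, and adjusted p = 0.0916 with an estimated correlation). Its examples Nfkb2 and Nfkbia, both of the NF-kappaB pathway, had slopes of 0.0152 and 0.0155, S100a9, an alarmin of neutrophils, 0.0307 and the cytokine Il18 -0.0237, and 0 members passed over all genes or adjusted over the list alone. The macrophage and red pulp list had a mean slope of 0.0102 with 19 of 25 members above 0 (adjusted p = 4.47e-04, and adjusted p = 0.468 with an estimated correlation). Of its members 2 rose adjusted over the list alone and 0 over all genes. The lysosomal protease Ctsd had a slope of 0.0462, the saposin precursor Psap 0.0405, the receptor Fcgr3 0.0261 and the cholesterol carrier Npc2 0.0159. The erythroid list had a mean slope of -0.0134 with 18 of 23 members below 0 (adjusted p = 9.81e-05, and adjusted p = 0.42 with an estimated correlation). None of its members passed over all genes or adjusted over the list alone: the alpha globins Hba-a1 and Hba-a2 had slopes of -0.0339 and -0.0365, the heme enzyme Alad -0.0283 and the transferrin receptor Tfrc -0.0132. The ER chaperone and unfolded protein response list had a mean slope of 0.00607 with 22 of 32 members above 0 (adjusted p = 0.0364, and adjusted p = 0.563 with an estimated correlation). Of its members 2 rose adjusted over the list alone and 0 over all genes, and its examples Hsp90b1, the ER chaperone GRP94, Ssr4, Pdia3 and Pdia4 had slopes of 0.0358, 0.022, 0.0265 and 0.0264. The adjusted p with label run as a block was 0.00778 for plasma cells, 8.01e-04 for both erythroid cells and macrophages, 0.00721 for inflammation and 0.0593 for ER chaperones. Within label runs the plasma cell, inflammation and ER slopes were positive in 5 of 5, the macrophage slope in 4 of 5, and the erythroid slope was negative in 4 of 5, with 0.0105 in the remaining run. The ER call was lost without any 1 of 14 mice (adjusted p from 0.0509 to 0.127). These were male middle-aged replicates 1 and 2, female middle-aged replicate 1, male old replicates 1, 2 and 3, female old replicates 1, 2 and 3, male and female young adult replicate 5, and male juvenile replicate 5 with female juvenile replicates 4 and 5. Hsp90b1 passed over all genes (adjusted p = 0.0361) without female old replicate 4, and Hsp90b1 (0.0337, adjusted p = 0.0123) and Pdia4 (0.0286, adjusted p = 0.00408) passed after subtraction of the local median. The Txndc5 call was lost (adjusted p from 0.0506 to 0.0893) without any 1 of male juvenile replicate 1, female juvenile replicates 1 and 4, male old replicates 1 and 2, and female old replicates 1, 3, 4 and 5.

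**Figure D1:**
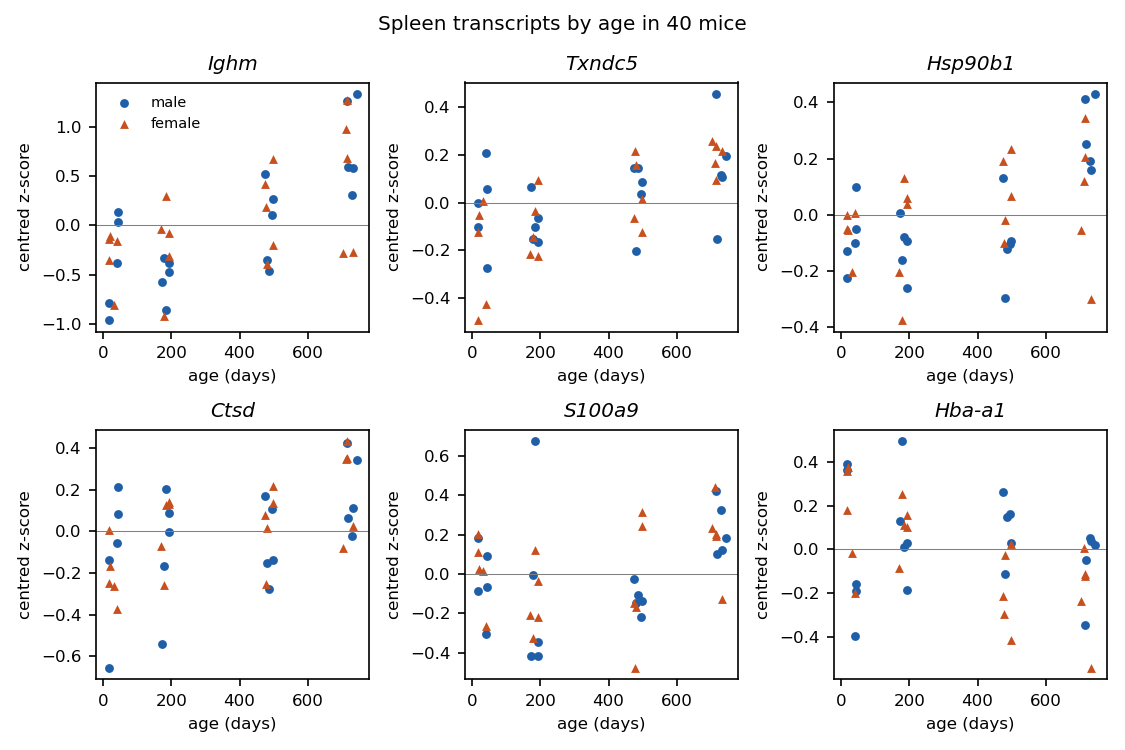
Centered score (array standard deviations, vertical axis) against age in days (horizontal axis) for 6 genes, with 1 point per mouse, males as circles and females as triangles. The mean of Ighm over the 10 mice of a class went from -0.353 in juveniles to 0.646 in old mice, and that of Hba-a1 from 0.0712 to -0.13.

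Across all spots, limma called 17 that rose and 0 that fell with age (1111 at unadjusted p under 0.05, a count that 18 of 100 regroupings of the mice reached), and 10 genes that rose and 0 that fell (529 genes at unadjusted p under 0.05). If no spot changed, 844.8 spots would be expected at unadjusted p under 0.05, here and in every comparison below. The fit with label run as a block called 18 that rose and 0 that fell. Of the 17 spots, 7 carried no gene name. Their positions were inferred from the correlation between spots that were neighbors in the numbering: 8 lay in panel 22 of array A and 7 in panel 4 of array B, and the other 2 were Txndc5 and an unnamed spot. In panel 4 of array B the called spots of Tle4, Cfap47, L3mbtl2, B3galt5, Irf2bpl and Pcnt lay along row 24 and column 12, which met at an unnamed called spot with a slope of 0.131. The mean score over the 40 mice was 0.519 at that spot, 1.82 at Ighm and from -1.11 to -0.477 at the spots of Tle4, Irf2bpl, B3galt5, Cfap47, L3mbtl2, Pcnt and Tgfbr3. In panel 22 of array A Ighm lay 4 rows from Tgfbr3 and Lrrc58. Pcnt, a centrosome protein singled out after its values were seen, rose at this spot by 0.0414 per 100 days (adjusted p = 0.0394), while its other 2 spots had slopes of 0.0083 and 0.0127. Without those 2 panels limma called 0 spots. The adjusted p of Txndc5 and of the unnamed spot outside them depends on how many spots pass beside them. The 0 calls are therefore no separate test of these 2 spots.

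**Figure D2:**
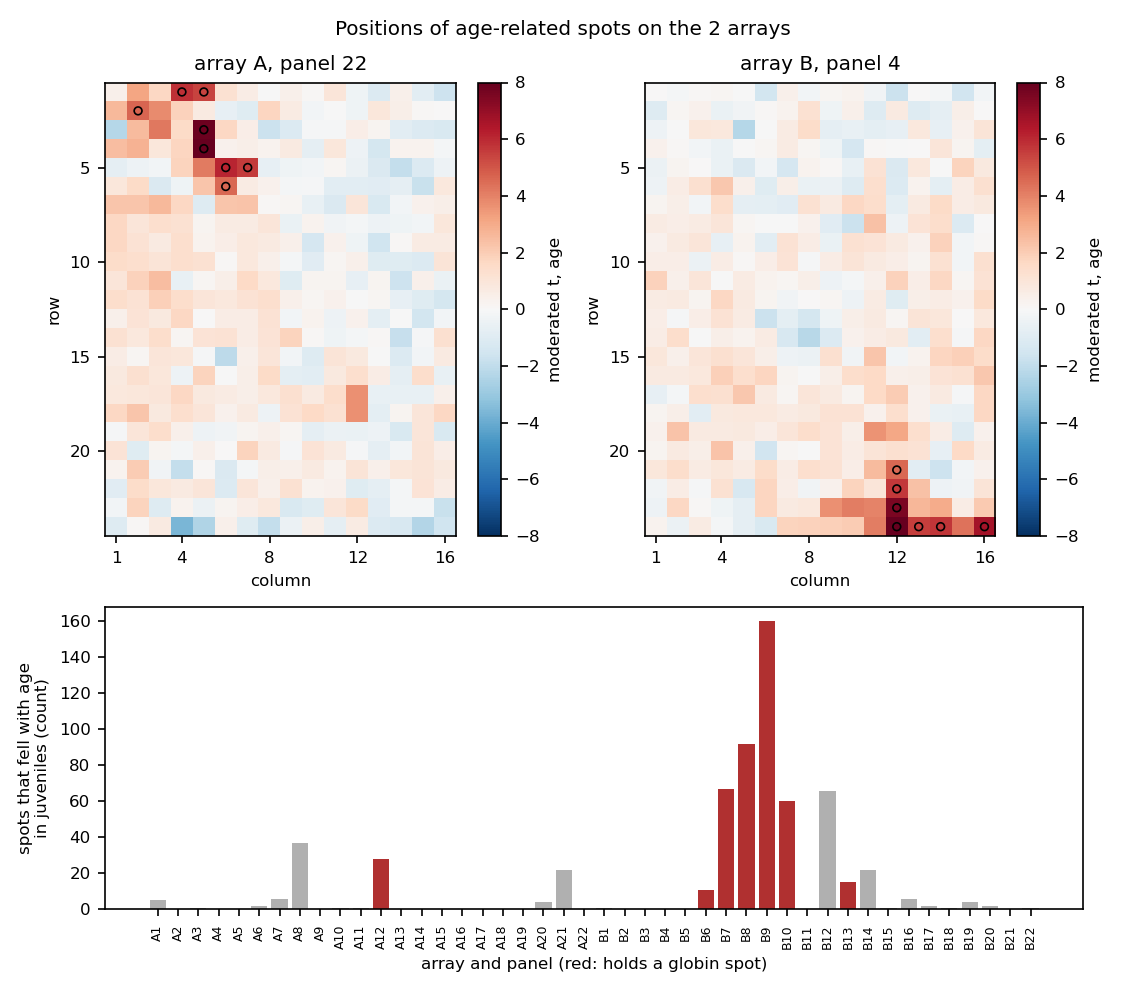
Upper maps show the moderated t statistic for age (color) of the 384 spots in panel 22 of array A and panel 4 of array B by inferred row and column, with circles on called spots; lower bars count the spots in each panel that fell with age among juveniles. The called spots lay close together in both maps, 8 on array A and 7 on array B, and the 7 panels with a globin spot (red bars) held 433 of the 618 falling spots.

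The comparison of young adults with juveniles addressed maturation of the spleen. No transcript or list passed. The genes with the highest statistics were Cflar, an inhibitor of death receptor signaling (0.352, SE 0.0923, n = 10 per class), the mitochondrial import factor Timm8b (0.269) and Tdrd3 (0.188), and those with the lowest were Rsl1d1, a nucleolar protein (-0.368), Zfp638 (-0.263) and the RNA exosome subunit Exosc8 (-0.175). Each had an adjusted p of 0.999. Cflar averaged -0.171 in juveniles, 0.181 in young adults, 0.0295 in middle-aged and -0.0405 in old mice. The list with the lowest adjusted p was stroma and extracellular matrix, with a mean difference of -0.0349 and 28 of 39 members below 0 (adjusted p = 0.0873). The limma fit called 0 spots and 0 genes (534 spots and 190 genes at unadjusted p under 0.05), and 0 spots with label run as a block. After subtraction of the local median of neighboring spots, 1 spot was called, that of Sparc, a collagen-binding matrix protein (-0.202, adjusted p = 0.0188).

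The comparison of middle-aged with young adult mice addressed the earlier part of adult aging. The plasma cell and immunoglobulin list was higher in middle-aged mice, with a mean difference of 0.123 and 4 of 6 members above 0 (camera adjusted p = 0.0354, and adjusted p = 0.0618 with an estimated correlation). The differences were 0.444 for Ighm, 0.173 for Xbp1, 0.124 for Creld2 and 0.0775 for Edem1, an ER degradation factor. The remaining members, Fkbp11 and Sdc1, were not above 0, and 0 members passed over all genes or adjusted over the list alone. The list mean was higher in 5 of 5 label runs (0.00625 to 0.275), but with label run as a block the adjusted p was 0.0971, and after subtraction of the local median it was 0.149 (mean difference 0.0854). The call was also lost (adjusted p from 0.0526 to 0.144) without any 1 of 11 mice. They were male young adult replicates 1 and 5, female young adult replicates 3, 4 and 5, male middle-aged replicates 1, 2 and 3, and female middle-aged replicates 1, 3 and 5. No single gene passed: the genes with the highest statistics were the scavenger receptor Stab1 (0.185), the complement inhibitor Serping1 (0.143) and the Mediator subunit Med6 (0.343). Those with the lowest were Spag7 (-0.233), the cytokine Il17f (-0.153) and 1600020E01Rik (-0.25), each with an adjusted p of 0.997. The limma fit called 0 spots (373 at unadjusted p under 0.05), 0 genes (169 at unadjusted p under 0.05) and 0 spots with label run as a block.

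The comparison of old with young adult mice covered the whole of adult aging. Ighm was higher in old mice by 1.02 (SE 0.193, n = 10 per class, adjusted p = 0.00657), by 1.34 in males and 0.686 in females. Tle4 was higher by 0.638 (SE 0.102), Tgfbr3 by 0.561 (SE 0.088) and Irf2bpl by 0.46 (SE 0.0725), each with an adjusted p of 7.23e-04. B3galt5 (0.473), L3mbtl2 (0.446), Lrrc58 (0.301) and Cfap47 (0.479) rose as well, and each of these 8 genes was higher in both sexes and in 5 of 5 label runs. No gene fell. Hsp90b1 was higher by 0.27 (SE 0.0698, adjusted p = 0.245) and passed without female old replicate 4 (adjusted p = 0.0265), and S100a9 by 0.328 (adjusted p = 0.812), passing without male young adult replicate 1 (adjusted p = 0.0207). Pdia4, below the threshold here, passed after subtraction of the local median (0.195, adjusted p = 0.0161). Cfap47 was lost (adjusted p from 0.0501 to 0.073) without any 1 of female old replicate 1, male old replicates 2 and 3, male young adult replicate 4 and female young adult replicate 5.

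Among the lists, which share some genes, 5 were higher and 1 lower in old than in young adult mice. The plasma cell and inflammation calls were kept with an estimated correlation and the other 4 were lost (adjusted p from 0.351 to 0.821). The inflammation list shares C1qa, C1qb and C1qc with the macrophage list and Lcn2 and S100a9 with the neutrophil list. The plasma cell list was higher by a mean of 0.24 with 6 of 6 members above 0 (camera adjusted p = 5.06e-04, and adjusted p = 0.00606 with an estimated correlation). Adjusted over the list alone 2 of its members rose and over all genes 1, Ighm, while Xbp1 differed by 0.182, Creld2 by 0.155 and Edem1 by 0.053. The inflammation and complement list was higher by 0.102 with 11 of 13 members above 0 (adjusted p = 5.06e-04, and adjusted p = 0.0261 with an estimated correlation). A single member, 1 of 13, rose adjusted over the list alone and 0 over all genes, and the differences were 0.125 for Serping1, 0.19 for the complement component C1qc, 0.129 for Nfkbia and 0.328 for S100a9. The ER chaperone list was higher by 0.0656 with 24 of 32 members above 0 (adjusted p = 5.08e-04, and adjusted p = 0.351 with an estimated correlation). Of its members 2 rose adjusted over the list alone and 0 over all genes: Ssr4, of the translocon-associated complex, differed by 0.185 and the disulfide isomerase Pdia4 by 0.215. The macrophage list was higher by 0.0755 with 20 of 25 members above 0 (adjusted p = 5.08e-04, and adjusted p = 0.579 with an estimated correlation), with Ctsd at 0.234, lysozyme Lyz2 at 0.17, progranulin Grn at 0.169 and Npc2 at 0.111, and 0 members passed over all genes or adjusted over the list alone. The erythroid list was lower by a mean of -0.0793 with 18 of 23 members below 0 (adjusted p = 5.06e-04, and adjusted p = 0.579 with an estimated correlation). Its members Alas2, the first enzyme of heme synthesis, Hba-a1, the carbonic anhydrase Car1 and Hba-x differed by -0.338, -0.232, -0.176 and -0.168, and 0 members passed either way. Ribosomal proteins were higher by 0.0392 with 49 of 63 members above 0 (adjusted p = 0.0427, and adjusted p = 0.821 with an estimated correlation), with Rpl36 at 0.157, Rpl10 at 0.104, Rps4x at 0.1 and Rps28 at 0.083, and 0 members passed either way. Within label runs the plasma cell and inflammation differences were positive in 5 of 5, and those of the other 4 lists kept their sign in 4 of 5. Fitted with label run as a block, the adjusted p was 8.07e-04 for plasma cells, 0.00115 for erythroid cells, 0.047 for ribosomal proteins and 6.95e-04 for the other 3. The macrophage call was lost without female old replicate 1 (adjusted p = 0.0519). The ribosomal call was lost without any 1 of 9 mice. The adjusted p was 0.581 without male old replicate 1, 0.081 without replicate 2, 0.999, 0.226 and 0.558 without female old replicates 1, 2 and 3, 0.0547 and 0.505 without male young adult replicates 2 and 5, and 0.0815 and 0.586 without female young adult replicates 1 and 5.

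The remaining lists did not pass in old against young adult mice. Among immune cell lists, neutrophils and granulocyte precursors had an adjusted p of 0.679, dendritic cells 0.689, the interferon response 0.489 and MHC class I presentation 0.169. Stroma and extracellular matrix had an adjusted p of 0.727 and endothelium 0.727, cell cycle genes 0.489, oxidative phosphorylation 0.489, the translation factors 0.689, antioxidant and iron handling 0.581, senescence and p53 targets 0.689, and sex-linked genes 0.489. Proteasome genes (adjusted p = 0.896) had a mean of 0.000301 and a median of 0.019 and a test direction of lower, and heat shock genes (adjusted p = 0.788) had a mean of -0.00354 and a median of 0.00775. The liver list had a mean of -0.0264 and a median of 0.028 (adjusted p = 0.689). Lists with under 5 measured genes were not tested: their mean differences were -0.0752 for 4 B cell genes, 0.066 for 4 T cell genes, 0.001 for the natural killer cell gene Eomes, 0.0957 for 3 MHC class II genes, -0.011 for 4 adipose genes and 0.059 for the pancreatic gene Cpa1. For 4 megakaryocyte genes the mean was -0.018 and the median 0.0285.

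Across all spots, limma called 15 that were higher and 0 that were lower in old than in young adult mice (830 at unadjusted p under 0.05, a count that 30 of 100 regroupings of the mice reached), and 8 genes that were higher and 0 lower (364 genes at unadjusted p under 0.05). A fit with label run as a block called 18 that were higher and 0 lower. Of the 15 spots, 8 lay in panel 22 of array A and 7 in panel 4 of array B, and 6 carried no gene name. After subtraction of the local median 6 of the 8 genes lost their call. These were Ighm (0.784, adjusted p = 0.253), B3galt5 (0.21, adjusted p = 0.16), Lrrc58 (0.233, adjusted p = 0.103), and Tgfbr3 (0.452), L3mbtl2 (0.175) and Cfap47 (0.294) with an adjusted p of 0.0845 each. Tle4 and Irf2bpl kept theirs.

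The comparison of old with middle-aged mice addressed the last part of adult life. Irf2bpl, a nuclear protein named for its similarity to an interferon regulatory factor partner, was higher in old mice by 0.384 (SE 0.0725, n = 10 per class, adjusted p = 0.0414), by 0.698 in males and 0.07 in females. That call was lost in 29 of the 40 fits that left out 1 mouse (adjusted p from 0.0501 to 0.152), and after subtraction of the local median (0.176, adjusted p = 1). B3galt5 (0.379, adjusted p = 0.115) and L3mbtl2 (0.35, adjusted p = 0.186) followed, and the genes with the lowest statistics were the activin subunit Inhba (-0.288), Serpina1e (-0.566) and the anaphase-promoting complex subunit Anapc11 (-0.122). Without female middle-aged replicate 1 or female old replicate 5, B3galt5 (adjusted p = 0.0218 and 0.0214) and L3mbtl2 (adjusted p = 0.0378 and 0.0157) passed, and B3galt5 also passed without male old replicate 1 (adjusted p = 0.0421) or male middle-aged replicate 2 (adjusted p = 0.0264). The neutrophil list was higher by a mean of 0.132 with 6 of 7 members above 0 (camera adjusted p = 0.00313, and adjusted p = 0.0324 with an estimated correlation). Its members include Lcn2 and Ltf, iron-binding proteins of granules, at 0.351 and 0.137, S100a9 at 0.297 and Anxa1 at 0.075. The macrophage list was higher by 0.065 with 23 of 25 members above 0 (adjusted p = 0.0021, and adjusted p = 0.343 with an estimated correlation). Ctsd differed by 0.209, Lyz2 by 0.139, Npc2 by 0.0587 and the lysosomal membrane protein Lamp2 by -0.176. The inflammation list was higher by 0.0775 with 10 of 13 members above 0 (adjusted p = 0.0112, and adjusted p = 0.196 with an estimated correlation), with the lipopolysaccharide-binding protein Lbp at 0.139 and Nfkbia at 0.116. The ER chaperone list was higher by 0.0421 with 28 of 32 members above 0 (adjusted p = 0.00355, and adjusted p = 0.343 with an estimated correlation), with Pdia4 at 0.188, Hsp90b1 at 0.187, Manf at 0.162 and Ssr4 at 0.134. The ribosomal list was higher by 0.0368 with 54 of 63 members above 0 (adjusted p = 0.0148, and adjusted p = 0.793 with an estimated correlation), with Rpl37a at 0.133, Rps24 at 0.0905, Rpl36 at 0.083 and Rps12 at -0.091. The erythroid list was lower by a mean of -0.0581 with 17 of 23 members below 0 (adjusted p = 0.0021, and adjusted p = 0.343 with an estimated correlation), with Alad at -0.137, Hba-x at -0.133, Tfrc at -0.0577 and the heme enzyme Uros at 0.064. In each of these 6 lists 0 members passed over all genes or adjusted over the list alone.

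Within label runs the neutrophil (0.059 to 0.191) and ER differences (0.0139 to 0.0867) of old against middle-aged mice were positive in 5 of 5. The erythroid, macrophage and inflammation differences kept their sign in 4 of 5 and the ribosomal difference in 3 of 5 (-0.155 to 0.157). With label run as a block the adjusted p was 0.00256 for neutrophils, 4.58e-04 for macrophages, 0.015 for inflammation, 0.0148 for ribosomal proteins, and 0.00265 for both erythroid cells and ER chaperones. Without female old replicate 1 the macrophage (adjusted p = 0.1) and inflammation (adjusted p = 0.0594) calls were lost and the ribosomal mean was -0.000573. The ribosomal call was also lost without male old replicate 1 (adjusted p = 0.785), female old replicates 2 (0.0672) and 3 (0.425), female middle-aged replicates 2 (0.808) and 5 (0.247), and male middle-aged replicates 3 (0.247) and 4 (0.126). Across all spots, limma called 0 (234 at unadjusted p under 0.05, lowest adjusted p = 0.0994), and 0 with label run as a block. At gene level 1 gene was called, Irf2bpl (101 genes at unadjusted p under 0.05), and its called spots in the trend and in old against young adult mice lay in panel 4 of array B. Without female old replicate 5 limma called 3 spots, and without male old replicate 1, male middle-aged replicate 2 or female middle-aged replicate 1 it called 1.

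The comparison of females with males asked which transcripts differed between the sexes across all ages. No transcript passed. Xist, the RNA that silences an X chromosome in females, was higher in females by 0.298 (SE 0.109, n = 20 per sex, unadjusted limma p = 0.00953, adjusted p = 1) and in 5 of 5 label runs. The other sex-linked genes showed small differences: Eif2s3x, Ddx3x, Kdm5c, Usp9x and Kdm6a, genes that escape X inactivation, at 0.0635, 0.0243, 0.011, 0.0044 and 0.00283, and the Y-linked Eif2s3y and Uty at -0.062 and -0.048. The sign of Kdm6a, Kdm5c and Usp9x depended on single mice, and Ddx3x, Kdm6a and Usp9x were negative on at least 1 of their spots. The sex-linked list had 6 of 8 members above 0 (camera adjusted p = 0.425). Those below 0 were the Y-linked Eif2s3y and Uty, so the signs were those that the sex labels call for. The list joins X-linked and Y-linked genes, so its test for 1 direction cannot check the labels. These genes were meant to check the sex labels. None passed, and some signs depended on single mice or spots, so the genes neither bear out nor contradict the labels. Whether these spots can show a difference between the sexes is unknown. The lack of called transcripts therefore does not show that the sexes were alike. Gpatch11 (0.13), Ppp1r12a (0.0913), Sepsecs (-0.117), Rab21 (-0.323) and Rnf6 (-0.119) had the other extreme statistics. Ribosomal proteins were lower in females by a mean of -0.0311 with 56 of 63 members below 0 (camera adjusted p = 0.00326, and adjusted p = 0.839 with an estimated correlation). Rpl3, Rpl24, Rpl7a and Rps29 differed by -0.107, -0.081, -0.0693 and -0.0465, and 0 members passed over all genes or adjusted over the list alone. With label run as a block the adjusted p was 0.00125, and after subtraction of the local median it was 0.447. The ribosomal call was lost (adjusted p from 0.052 to 0.329) without any 1 of 9 mice. These were male young adult replicate 1, male old replicate 1, male middle-aged replicate 2, female juvenile replicate 5, female young adult replicate 5, female middle-aged replicates 2 and 5, and female old replicates 4 and 5. The limma fit called 0 spots (98 at unadjusted p under 0.05), 0 genes (50 at unadjusted p under 0.05) and 0 spots with label run as a block.

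Whether age acted differently in females and males was asked by the difference of their age slopes and by the difference of their old minus young adult changes. Ribosomal proteins were called in both tests with camera at the preset correlation, and with an estimated correlation both calls were lost (adjusted p = 0.954 for the slopes and adjusted p = 0.914 for the changes). Their old minus young adult difference was 0.14 in males, from -0.051 ± 0.129 to 0.0888 ± 0.155, and -0.0614 in females, from 0.0136 ± 0.109 to -0.0478 ± 0.258 (SD of list means, n = 5 per group). The female minus male contrast of these changes was -0.201 with 60 of 63 members below 0 (camera adjusted p = 7.15e-08, and adjusted p = 0.914 with an estimated correlation), with Rpl32 at -0.418, Rps12 at -0.402, Rps28 at -0.286 and Rps21 at -0.279. The slopes differed by -0.0184 per 100 days with 57 of 63 members below 0 (adjusted p = 0.0043, and adjusted p = 0.954 with an estimated correlation), with Rpl32 at -0.0449, Rps12 at -0.0447, Rps27l at -0.0424 and Rps23 at -0.0413. That call was lost without male old replicate 1 (adjusted p = 0.454), female old replicate 4 (0.406) or female old replicate 5 (0.296), and after subtraction of the local median (adjusted p = 0.476). The macrophage list differed by 0.173 between old and young adult males and by -0.0224 in females, a contrast of -0.196 with 21 of 25 members below 0 (adjusted p = 0.00755, and adjusted p = 0.914 with an estimated correlation). C1qa and C1qc, subunits of complement C1q, were at -0.508 and -0.404, the receptor kinase Axl at -0.488 and the tetraspanin Cd81 at -0.342. Its call was lost without male old replicate 2 (adjusted p = 0.0643) or female old replicate 4 (adjusted p = 0.114).

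No single transcript passed either test of age by sex, and in the lists named 0 members passed adjusted over the list alone. In the contrast of old minus young adult changes, Klf7 (0.453), AU018091 (0.448), Rab24 (0.484), Stra6 (-0.354), Cdkn3 (-0.368) and Dio3os (-0.432) had the extreme statistics, each with an adjusted p of 0.603. Among the slopes these were Lrp2bp (0.0907), cyclin D3 Ccnd3 (0.0613), Ccar2 (0.061) and Lrrfip1 (-0.0506), each with an adjusted p of 0.254, followed by Icmt (-0.0388) and Klhdc4 (-0.0569) at 0.299. Without female old replicate 1 Lrp2bp and Ccar2 passed (adjusted p = 0.024), as did Ccnd3, Lrrfip1 and Icmt (adjusted p = 0.0461), and Ccnd3 also passed without female old replicate 2 (adjusted p = 0.0496). The limma fit called 0 spots for the slopes (2368 at unadjusted p under 0.05, lowest adjusted p = 0.265; 902 of the genes) and 0 for the contrast (1660 at unadjusted p under 0.05, lowest adjusted p = 0.489; 575 of the genes). It called 0 in both with label run as a block (3321 and 2700 at unadjusted p under 0.05). Without the block, 9 of 100 splits of the mice, the real one included, reached the 2368 of the slopes. For the 1660 of the contrast 18 of 100 did.

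The juvenile class spanned weaning and puberty, and the fit of age within it asked what changed from 17 to 44 days. Several transcripts of red cell precursors were among those that fell. Alas2 fell by 0.437 per 10 days (SE 0.0534, n = 10 mice, adjusted p = 0.00856), from a mean of 0.49 ± 0.253 in the 5 mice of 17 to 21 days to -0.43 ± 0.171 in the 5 mice of 33 to 44 days. Car2, a red cell carbonic anhydrase, fell by 0.342 (SE 0.0411), Cd24a, a surface glycoprotein of erythroblasts and immature B cells, by 0.39 (SE 0.0468), and Ubac1 by 0.386 (SE 0.0446), each with an adjusted p of 0.00856. Hba-a1 fell by 0.242 and the blood group gene Rhd by 0.269 (adjusted p = 0.0123 for both), and the peroxidase Gpx1 by 0.352 (adjusted p = 0.0123). For Alas2, Car2, Cd24a, Ubac1, Gpx1, Hba-a1, Rhd, Ccna2, Hmgb2 and Gpx4 the ranges of the younger and the older juveniles did not overlap. These genes were picked by their age statistics in the same mice, so this is no separate support. Ranges also did not overlap for Atp5b, Eef1g, Eif5a and Psmd11, which did not pass. They overlapped for Cd74, Psap, Stmn1, Psrc1 and Mcrs1, and the share over all genes was not counted. Cd74, the MHC class II invariant chain, rose by 0.248 (SE 0.049, adjusted p = 0.0221), from -0.324 ± 0.266 to 0.13 ± 0.168, and Psap by 0.209 (SE 0.0461, adjusted p = 0.0331).

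The erythroid list fell, with a mean slope of -0.154 per 10 days and 21 of 23 members below 0 (camera adjusted p = 1.69e-14, and adjusted p = 0.0763 with an estimated correlation). Of its members 15 fell adjusted over the list alone and 8 over all genes. The cell cycle list fell, with a mean slope of -0.0413 and 53 of 84 members below 0 (adjusted p = 0.0303, and adjusted p = 0.669 with an estimated correlation). Of its members 10 fell adjusted over the list alone and 4 over all genes, namely cyclin A2 Ccna2 (-0.3), Hmgb2 (-0.25), the tubulin regulator Stmn1 (-0.216) and Hmgn2 (-0.182). The antioxidant and iron list fell, with a mean slope of -0.064 and 19 of 29 members below 0 (adjusted p = 0.00461, and adjusted p = 0.669 with an estimated correlation). Adjusted over the list alone 8 fell and over all genes 3, the peroxidases Gpx1 (-0.352) and Gpx4 (-0.244) and the glutathione transferase Gstm1 (-0.172), and Prdx3 was at -0.237 (adjusted p = 0.0666). The means were -0.0296 for oxidative phosphorylation (42 of 62 members below 0, adjusted p = 0.0309), -0.0397 for proteasome (22 of 31, adjusted p = 0.0309) and -0.0293 for translation factors (30 of 47, adjusted p = 0.0461), and each had an adjusted p = 0.669 with an estimated correlation. Over all genes the respiratory complex I subunits Ndufa13 (-0.183) and Ndufa8 (-0.168), the proteasome subunit Psma2 (-0.244), Eif1ad (-0.263) and the elongation factor Eef1b2 (-0.128) fell. Adjusted over the list alone 3 fell for oxidative phosphorylation, 2 for proteasome and 7 for translation. Atp5b (-0.164, adjusted p = 0.0559), Ndufa7 (-0.113), Psmd7 (-0.129, adjusted p = 0.0661), Psmd4 (-0.0849), Psmd11 (-0.0797), Eif5a (-0.113, adjusted p = 0.0528) and Eef1g (-0.13, adjusted p = 0.0776) did not pass. Prdx3 passed without male replicate 1 (adjusted p = 0.0274), and Atp5b (0.0444), Ndufa7 (0.0478) and Psmd7 (0.0278) passed without male replicate 2. The 3 MHC class II genes had a mean slope of 0.148, and 2 of them rose adjusted over the list alone and 1, Cd74, over all genes. The 4 B cell genes had a mean of -0.0989, with Cd24a the member that fell over all genes, and the macrophage list a mean of 0.0218 (adjusted p = 0.177), with Psap rising. With label run as a block the adjusted p was 1.58e-11 for erythroid cells and 0.0286 for both cell cycle and antioxidant genes, and the macrophage list passed (higher, adjusted p = 0.0345), but it was 0.188 for oxidative phosphorylation and translation and 0.277 for proteasome. These 3 calls were also lost after subtraction of the local median (adjusted p = 0.198 for oxidative phosphorylation, 0.377 for proteasome and 0.562 for translation).

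**Figure D3:**
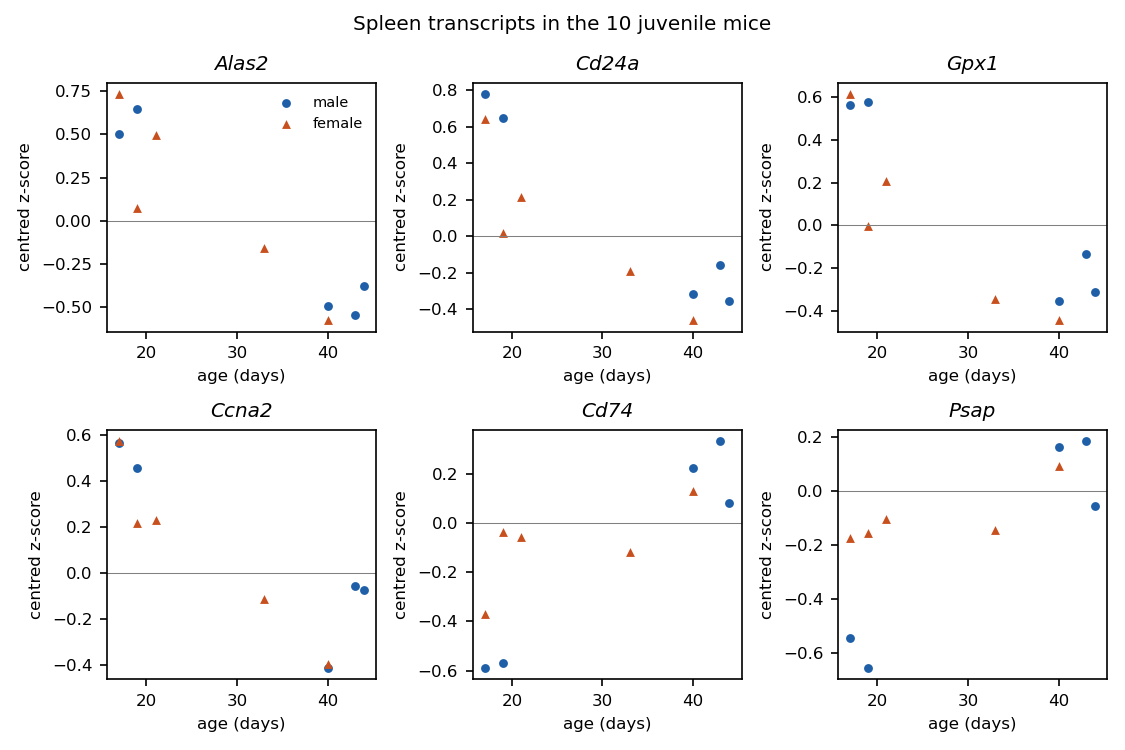
Centered score (array standard deviations, vertical axis) against age in days (horizontal axis) for 6 genes in the 10 juvenile mice, with 1 point per mouse, males as circles and females as triangles. For Alas2 the 5 mice of 17 to 21 days averaged 0.49 and the 5 mice of 33 to 44 days averaged -0.43; Cd74 averaged -0.324 and 0.13.

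Each label run held 1 male and 1 female juvenile, 26, 25, 2, 23 and 7 days apart in runs 1 to 5. The older minus the younger mouse differed for the erythroid list by -0.347, -0.111, -0.122, -0.471 and -0.0848, and for Alas2 by -1.28, -0.45, -0.15, -1.08 and -0.34. For Cd74 the differences were 0.7, 0.12, 0.51, 0.72 and 0.34. Car2, Cd24a, Gpx1 and Psap also kept 1 sign in all 5 runs. Other items turned in 1 run: Hba-a1 was at 0.0158 in run 3, and in run 5 Ubac1 was at 0.01, the cell cycle list at 0.0423 and the antioxidant list at 0.0409. In run 2, with mice 25 days apart, these 2 lists differed by -0.00142 and -0.0112. The other genes that fell with the largest statistics were E2f6 (-0.261), Peak1 (-0.294), Acad11 (-0.252), the glucose transporter Slc2a4 (-0.257), Trim32 (-0.261), Nae1 (-0.366) and 4930562C15Rik (-0.242), and those that rose were Psrc1 (0.216), Mcrs1 (0.168) and Frmpd1 (0.13). Car2 had 2 spots with opposite slopes, -0.736 and 0.0515. Across all spots, limma called 15 that rose and 618 that fell with age in juveniles (2019 at unadjusted p under 0.05), and 5 genes that rose and 247 that fell. The count of 2019 was reached in 16 of 100 splits of the mice, the real one included. With label run as a block 168 spots rose and 646 fell, and 518 of the 633 stayed called in the same direction. When ages were exchanged between the 2 mice of a run, 4 of the 32 arrangements, the real one included, called at least as many in that fit. The falling spots were not spread evenly: 433 of 618 (70.1%) lay in the 7 panels that hold a globin spot, which make up 15.9% of all spots. After subtraction of the local median limma called 43 spots, 9 that rose and 34 that fell, among them spots of Alas2 (-0.378), Gpx1 (-0.294), Ccna2 (-0.348), Hmgb2 (-0.196) and Car1 (-0.211). Hba-a1 (-0.0843, adjusted p = 0.17), Rhd (-0.0755, adjusted p = 0.274), Cd74 (0.188, adjusted p = 0.0793) and Psap (0.188, adjusted p = 0.124) no longer passed. Other named genes lost their call as well, many with far smaller slopes: Nae1 (-0.0503), Slc2a4 (-0.0532), Trim32 (-0.0774), Peak1 (-0.125), Psma2 (-0.0536), Stmn1 (-0.0546), Gpx4 (-0.0645), Gstm1 (-0.0295), Eif1ad (-0.0416), Ndufa13 (-0.0337), Ndufa8 (-0.0243), Eef1b2 (-0.0107), Psrc1 (0.101), Mcrs1 (0.0548) and Frmpd1 (0.0476), with an adjusted p from 0.0662 for Peak1 to 0.905 for Eef1b2. The slope of Hmgn2 turned to 0.022, and Psmd4 and Eif5a, below the threshold before, had slopes above 0. The call of Hba-a1 was also lost after quantile normalization (-0.104, adjusted p = 0.254).

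The juvenile counts rested on single mice. Without male replicate 3, a mouse of 19 days, limma called 1 spot and no gene named here kept its call. The adjusted p was then 0.0808 for Ubac1, Cd24a, Car2, Alas2, E2f6, Gpx1, Peak1, Acad11, Slc2a4, Trim32, Nae1, 4930562C15Rik, Hba-a1, Rhd, Hmgb2 and Ccna2, and from 0.0823 to 0.166 for the others. Without female replicate 4, a mouse of 40 days, 240 spots were called, and of these genes Ubac1, Cd24a, Car2 and Alas2 kept their call. The count was 317 without female replicate 1, 406 without female replicate 3 and 365 without male replicate 4. Cd74 was lost without female replicate 1 (adjusted p = 0.0603), male replicate 3 (0.116), male replicate 4 (0.0886) or female replicate 4 (0.0618). Without female replicate 1, the calls of Psap (adjusted p = 0.0603), Stmn1 (0.052), Ndufa13 (0.0674), Gpx4 (0.0603), Gstm1 (0.076), Ndufa8 and Hmgn2 (0.092), Psrc1 (0.0993), Frmpd1 (0.0766), Mcrs1 and Eef1b2 (0.116) were lost as well. Calls were lost without any 1 of the 10 mice for Frmpd1 (adjusted p from 0.0517 to 0.166), in 9 fits for Psrc1, Mcrs1, Hmgn2 and Eef1b2, in 8 for Ndufa8, in 7 for Psap and Gstm1, in 5 for Gpx4 and in 4 for Stmn1 and Ndufa13. The cell cycle list was lost without female replicate 1 (adjusted p = 0.0589), male replicate 2 (0.125) or male replicate 4 (0.158). Oxidative phosphorylation and proteasome were lost without female replicate 1 (0.0589 and 0.0718), male replicates 2 (0.0722 and 0.068), 4 (0.147 and 0.158) and 5 (0.0722 for both) or female replicate 5 (0.0739 and 0.106). Translation factors were lost without any of these 5 or female replicates 2 and 3, with an adjusted p from 0.05 to 0.158.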

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

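The tests of a smooth local signal as the whole source, of a spread from 1 strong spot per membrane, of label run in juveniles, and of splits within label runs were chosen after the result was seen, and the minimum of 5 spots for the test of other spots was added after their number was known.

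Of 144 groups examined, 10 had 1 sample far from the others of its group, and chance flags about 1 in 20 groups. Tle4 was -0.623 in female young adult replicate 5, against -0.223 to -0.0828 in the others. Tgfbr3 was -0.293 in female middle-aged replicate 2, against 0.107 to 0.207. L3mbtl2 was 0.294 in male old replicate 1, against 0.474 to 0.544. In female juvenile replicate 5 the plasma cell list mean was -0.17, against -0.0553 to -0.027, and the ribosomal list mean was -0.222, against -0.00412 to 0.0811. The median correlation with the other arrays was low in male young adult replicate 5 on array A (0.891, against 0.964 to 0.965) and array B (0.848, against 0.969 to 0.974). It was also low in female young adult replicate 5 on array A (0.937, against 0.969 to 0.971), and in male juvenile replicate 5 (0.969, against 0.97 for the others) and female middle-aged replicate 2 (0.92, against 0.964 to 0.976) on array B.

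In the tests of age by sex 3 list results were flagged, and each call was lost with an estimated correlation. The ribosomal slopes differed by -0.0184 per 100 days (adjusted p = 0.954 with an estimated correlation, and adjusted p = 0.476 after subtraction of the local median). The female minus male contrast of the old minus young adult changes was -0.201 for ribosomal proteins and -0.196 for macrophages (adjusted p = 0.914 with an estimated correlation for both). With camera at the preset correlation, both contrasts stayed called after subtraction of the local median (adjusted p = 1.4e-05 and 0.00405).

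The first pattern is that the spots rising with age lay side by side on each membrane. The tables argue against a local signal smooth over 2 steps as the whole source, since 8 of the 17 called spots stayed past the threshold after the local median was subtracted, a correction that leaves a narrower spread in place. Signal shared between neighboring spots remains open: the median age t of the 57 uncalled spots 1 step away was 1.64, above all 99 shifted placements (highest 0.974). That value decides little, because the called spots were picked for a high t. Residuals of spots 22 numbers apart correlated at a median of 0.645 on array A and 0.613 on array B, so neighbors of such spots tend to follow them. A spread from 1 strong spot per membrane stays open and undecided: the median age t 1 step from the strongest spot (Ighm on array A, an unnamed spot on array B) exceeded that beyond 4 steps by 3.5, but the spot was picked inside the area, and from 1 to 3 steps the median was 1.82, 2.53 and 0.582 on array A and 4.11, 2.35 and 0.588 on array B. An age change of each named transcript cannot be told apart from it, because the other panels hold 2 further spots of the genes with a called spot, both of Pcnt (median t 1.23, above 95 of 100 random sets), and the spot of Znrf2 outside the area had a t of 1.01 (adjusted p = 0.886).

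The second pattern is that spots falling with age in juveniles lay in the panels of globin spots. With label run as a block, which removes shifts between runs, 81.8% of the called spots kept their call and sign. In that fit 4 of the 32 exchanges of ages within runs, the real one included, called at least as many spots. Calls kept there therefore cannot decide whether label run is the source. Spread from globin spots is a candidate explanation: the median t within 2 steps of a globin spot was lower than beyond 4 steps in the same panels by a difference of -3.79, against at least -2.35 in shifted placements. A fall of erythroid transcripts themselves is open too and compatible with it, as the 19 erythroid genes other than globins had a median t of -3.05 after the local median was subtracted, below all 10000 random lists. Random lists ignore that erythroid genes can move together over the mice. The erythroid list lost its call with an estimated correlation, and the named genes lost theirs without male juvenile replicate 3. Spread from globin spots and a fall of erythroid transcripts may hold at once, and the development of the spleen from 17 to 44 days remains an untested hypothesis.

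The third pattern is that the plasma cell and ER chaperone lists were higher in old than in young adult mice. After subtraction of the local median the camera adjusted p was 6.03e-04 for plasma cells and 1.74e-04 for ER chaperones, at the preset correlation alone. This argues against a local signal smooth over 2 steps as the whole source. A narrower sharing between neighbors stays open, since the correction leaves it in place and the plasma cell list still held Ighm. The plasma cell list without Ighm, 5 genes, had an unadjusted camera p of 0.013 at the preset correlation (n = 10 mice per class). It was not run with an estimated correlation, and its genes include Xbp1, Creld2 and Edem1 of the ER list. It is therefore limited evidence against Ighm alone as the source. Every label run held a mouse of each group, so shifts between runs cannot create a difference between old and young adult mice. The ER list with label run as a block (camera adjusted p = 6.95e-04) is therefore no test of label run as the source. More antibody-secreting cells in old spleens may account for both lists, a hypothesis found and tested on the same data. It remains open for the ER list, which had an adjusted p of 0.351 with an estimated correlation, and the lists share Xbp1, Creld2 and Edem1. Beside Ighm and these shared genes the plasma cell list held Fkbp11 and Sdc1, which were not above 0 in middle-aged against young adult mice.

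Among 100 splits of the mice, the real one included, 3 gave at least as many called spots as the 17 of the age trend (highest other 4094) and 3 as many as the 15 of old against young adult mice (highest other 4084), and for juveniles 2 gave as many as the real 633 (highest other 875). These splits mixed label runs, and those that called 4094 or 4084 spots point to a structure of the samples apart from age. Splits within label runs were therefore drawn, with label run as a block in the fit. Of 100 such splits, 1, the real one, gave as many as the 18 spots of the age trend (highest other 0), and 3 gave as many as the 18 of old against young adult mice (highest other 150). Both shares are under 0.05. These splits were chosen after the first ones were seen, and most called spots lay in 2 small areas, so this is limited evidence against chance. For the counts at unadjusted p under 0.05 in the same fits the shares were above 0.05. There 8 splits reached the 1838 of the age trend (highest other 2533) and 26 the 1369 of old against young adult mice (highest other 3871). In juveniles 4 of the 32 possible exchanges gave as many as the 814 of that fit (highest other 922), so chance was not excluded; runs 3 and 5 pair mice 2 and 7 days apart, whose exchange alters the ages little. For the other comparisons the real count of called spots was 0, so that 100 of 100 splits reached it by construction and that count tested nothing. The counts at unadjusted p under 0.05 were reached by 49 splits for young adults against juveniles and 68 for middle-aged against young adult mice. They were reached by 74 for old against middle-aged mice, 99 for sex, 9 for the difference of slopes and 18 for the contrast of changes, the real split included. The highest other split called 1 spot for young adults against juveniles, 466 for middle-aged against young adult mice, 27 for old against middle-aged mice, 216 for sex, 985 for the difference of slopes and 3 for the contrast of old minus young adult changes.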

How the results depend on the processing

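Subtraction of the local median and leaving out panels were tests chosen after the result was seen. The 17 spots of the age trend became 8 without the dimmest spots, 129 with array weights (64 up and 65 down), 10 at gene level, 6 with log2 of age (5 up and 1 down), 11 in adults alone and 0 without the 2 panels of the called spots. The 15 spots of old against young adult mice became 6 without the dimmest spots, 39 with array weights, 8 at gene level, 9 with the mice compared alone, 9 after subtraction of the local median and 0 without the 2 panels. Gene-level fits test fewer features and leave out unnamed spots, and the fits without panels leave out called spots. For the other settings the cause was not tested. Of the 17 spots 2 lay outside the panels left out and lost their call there too. Their adjusted p depends on how many spots pass beside them, so taking out the other called spots raises it by itself. The 0 calls without the panels are therefore no separate test of these 2 spots. Young adults against juveniles gave 1 after subtraction of the local median, middle-aged against young adult mice 1 with array weights, and old against middle-aged mice 1 with the array median subtracted, 8 with array weights, 1 with adjustment within each table and 1 at gene level. The 633 spots of juveniles became 252 at gene level, 43 after subtraction of the local median and 121 without the panels of globin spots. Counts under the remaining settings stayed within 1.5 times: 12 to 18 for the age trend (16 after subtraction of the local median, 12 up and 4 down, of which 8 were shared), 13 to 18 for old against young adult mice, and 555 to 899 for juveniles. These include quantile normalization (16, 15 and 555) and label run as a block (18, 18 and 814, the last with 168 up and 646 down). Leaving out each mouse in turn gave 12 to 19 for the age trend, 12 to 17 for old against young adult mice, 0 to 3 for old against middle-aged mice, 1 to 771 for juveniles, and 0 to 0 for each of the other 5 comparisons. Female against male mice compared alone is the primary fit itself, and the mouse with the conflicting description is no juvenile, so neither gave a further value. The plasma cell and neutrophil lists fell under 5 genes without the dimmest spots and gave no value.

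Signs turned in a few named results, and the cause was not tested. After subtraction of the local median, Kdm6a in females against males was -0.00534, Rps12 in the difference of slopes 0.00444, and Hmgn2, Psmd4 and Eif5a in juveniles 0.022, 0.00559 and 0.0337. On a single spot, Tfrc (0.033) and Npc2 (-0.06) turned in old against middle-aged mice, Ddx3x (-0.07), Kdm6a (-0.026 and -0.007) and Usp9x (-0.045 and -0.006) between the sexes, and Car2 (0.0515) in juveniles. Leaving out each mouse gave -0.0125 to 0.0278 for Kdm5c, -0.00683 to 0.0113 for Kdm6a, -0.00313 to 0.0086 for Usp9x, and -0.000573 to 0.0719 for ribosomal proteins in old against middle-aged mice. For named genes and lists, 425 values kept direction and side of the threshold under other settings, 95 lost the call, 3 gained one and 5 turned. Leaving out mice gave 6807, 238, 19 and 16, and single spots gave 144, 3, 5 and 8. With fry the calls kept were those of plasma cells in the age trend (adjusted p = 4.50e-04), middle-aged (0.0269) and old against young adult mice (1.14e-04), of inflammation in the age trend (0.0345) and old against young adult mice (0.00785), and of erythroid cells in juveniles (0.00153). All other list calls were lost with fry, in every comparison, with an adjusted p from 0.113 to 0.855. Camera after subtraction of the local median was run at the preset correlation alone. It kept every list call of the age trend and of old against young adult and middle-aged mice. Lists that passed there but not before were ribosomal proteins in the age trend (adjusted p = 3.79e-04) and macrophages in the difference of slopes (0.0328). In old against middle-aged mice they were dendritic cells (0.00264) and stroma (0.0296). Signal over background is not given for these arrays, so what it limits is unknown.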

Other observations

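No test in this part was planned: the spots described here were chosen after the result was seen. After subtraction of the local median of neighboring spots, limma called further spots that changed with age over the 40 mice, and the values here are of single spots. Chaperones of the endoplasmic reticulum were among those that rose: 1 of the 2 spots of Hsp90b1, the chaperone GRP94, by 0.0317 per 100 days (adjusted p = 0.00277) and Pdia4 by 0.0286 (adjusted p = 0.00544), next to Txndc5 at 0.0292 (adjusted p = 0.0171). Cd63, a tetraspanin of lysosomes, rose by 0.0288 (adjusted p = 0.0127) and the kinase Cdk12 by 0.0246 (adjusted p = 0.0197). Sparc, a collagen-binding matrix protein, fell by 0.0354 (adjusted p = 0.00121) and Oat, ornithine aminotransferase, by 0.0277 (adjusted p = 0.0449). In old against young adult mice, that spot of Hsp90b1 (0.23, adjusted p = 0.00366; both spots together 0.204, adjusted p = 0.0887), Pdia4 (0.195, adjusted p = 0.0248) and a spot of the X-linked deubiquitinase Usp9x (0.252, adjusted p = 0.028) were higher.

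In juveniles, with the local median subtracted, the erythroid genes Car2 (-0.347, adjusted p = 0.0157), Alas2 (-0.378, adjusted p = 0.0257) and Car1 (-0.211, adjusted p = 0.0308) fell per 10 days. Blvrb, a biliverdin reductase, at -0.276 (adjusted p = 0.0615), the anion exchanger Slc4a1 at -0.149 (adjusted p = 0.0789), and Fech, which inserts iron into heme, at -0.141 (adjusted p = 0.088) did not pass at gene level. Before that correction, Blvrb had fallen by 0.306 (adjusted p = 0.0154). Panels without a named globin spot also held many falling spots: 66 in panel 12 and 22 in panel 14 of array B, and 37 in panel 8 and 22 in panel 21 of array A.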
